A study of Drosophila melanogaster with 13 samples.

How the data were processed

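Per the labels' protocols, total RNA was isolated from ovaries of knockdown females, and small RNAs of 19 to 28 nt were cloned with adapters for multiplexed sequencing. Each of the 13 libraries came with a table that listed every different sequence once, with its length, 1 annotation name and a value. The genome build named in the labels was dm3. The aligner, the mismatches allowed, the source of the annotation and the order in which annotations were given to a sequence are not given in the sources used here. The values the authors deposited are a signal, read counts multiplied by 1 factor per library. Every value was a whole multiple of the smallest value of its library within 0.1%, so whole reads were recovered by dividing by that value. The deposited values sum to 1000000 in the nos-w and tj-w libraries and to other totals in the knockdowns. What the factor of a knockdown was set from is not stated. Read lengths ran from 18 to 29 nt.

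Reads were grouped by their annotation names. The 193 transposon names were joined into 135 families by merging the internal part and the terminal repeats of an element. Families are named here by their common names. The annotation spells Rt1a and Rt1b as DMRT1A and DMRT1B, and TART-B as TART_B1. DM412 and DM176 are its names for elements otherwise called by a number. Reads of 23 to 28 nt were taken as piRNA-sized and reads of 21 nt as siRNA-sized. The files give no genomic position or strand, so uniquely placed reads, antisense reads, the piRNA clusters and strand bias were not analysed here, and gene reads are sums over both strands.

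Levels were expressed relative to the reads of miRNA genes and compared with the w library of the same driver, giving 11 comparisons. Library depth ran from 5199559 to 14894764 reads, with 949138 to 2139955 miRNA reads in the nos-GAL4 libraries and 783628 to 1725895 in the tj-GAL4 libraries. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and ratios carry exact conditional intervals of the same kind from the read counts of both libraries. PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. A family was counted with at least 100 reads in the 2 libraries together. It was called lower or higher at 2-fold or more with an interval that excluded no change. The same rule was used for gene parts and for 21 nt reads. With 1 library per group there was no test of any difference. The knockdowns of a driver share 1 control library, so their ratios are not independent of each other.

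Before the data were examined, the comparisons, the size range, the thresholds, the transposon lists, the miRNA markers, the rule for named families and a set of alternative settings were fixed. The germline list held 48 families, of which 41 were matched to the annotation, the soma list 8 of 8 and the intermediate list 11 of 12. The unmatched members were X-element, Juan, hopper, aurora-element, springer, Stalker and a DNA transposon named by a number. The annotation's TART stood for TART-A and TART-C together. A list was described by its median log2 ratio, with a pseudocount of 1 read, and by the percentile of that median among 10000 random lists of the same size, drawn within 5 abundance classes. Named in the text are list members, target genes, the tj 3' UTR and siRNA loci, and per knockdown the 10 families with the largest fall and the 5 with the largest rise among those with at least 1000 reads. Any other feature is named as chosen after its value was seen.

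Ping-pong pairs were found as sequences of a family whose 5' ends are reverse complements. Overlaps of 10 to 20 nt were compared, 11 in all, because shorter ones match by chance without positions. The shares of reads that start with U or carry A at position 10 were counted over both strands. The planned range of overlaps from 1 nt was not used. For 21 nt reads, the overlap of 19 nt that Dicer products have was counted in the same way.

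The calls were tested on simulated data, made by drawing reads for both libraries from one profile and changing chosen items by 3-fold or 4-fold. In both simulated comparisons every changed family or gene part with enough reads was called, and no unchanged one was. The simulation held only counting error and changes above the 2-fold limit. It held no variation between libraries, so it gives no rate of false calls for these data. Of 100 gene parts lowered 4-fold, only 25 had enough reads in each comparison, against 100 and 75 of those raised, so falls of gene parts are undercounted. Simulated overlaps at random gave close to an even share. Alternatives varied the scaling, the size range, the counting of copies, the minimum of reads, the pseudocount, the control library and the depth. Different sequences counted once were still set against miRNA reads with their copies. Their number need not grow in proportion to reads, so this setting can lower ratios in libraries with more miRNA reads. The authors' scaling, a scaling to the list of the untargeted cell type, and a version of the tj-GAL4 comparisons limited to 24 to 28 nt piRNAs and to miRNA reads of 22 and 24 nt were chosen after seeing the data, as were the other scalings of the lists, of 21 nt reads and of gene reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.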

Results

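Small RNAs were sequenced from ovaries of Drosophila melanogaster females in which a UAS hairpin against 1 gene was driven either in germ cells (nos-GAL4) or in the somatic follicle cells around them (tj-GAL4). The 13 libraries comprised 7 made with nos-GAL4 and 6 made with tj-GAL4. Under nos-GAL4 the hairpins targeted w, fs(1)Yb (yb in the library names), armi, Gasz, spn-E, aub and del. Under tj-GAL4 they targeted w, fs(1)Yb, armi, Gasz, spn-E and zuc. The gene w encodes an eye pigment transporter and served as the control of each driver. There was 1 library per group, so no spread between replicates could be measured, no test was run, and each interval covers counting error only. Depth ranged from 5199559 to 7862148 reads in the nos-GAL4 libraries and from 8372587 to 14894764 reads in the tj-GAL4 libraries.

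The hairpins left siRNAs that matched the library names. Reads of 21 nt on exons of Gasz reached at least 37077 per 1000000 miRNA reads in both Gasz knockdowns, 114 times the highest level in any other library. The same margin was 416-fold for zuc, 107-fold for del, 23.96-fold for fs(1)Yb, 11.9-fold for armi and 6.82-fold for w. It was narrower for aub, at 3.77-fold, and for spn-E, at 2.10-fold, because tj-gasz and tj-zuc also held reads of these genes. Over 21 to 23 nt, a range chosen after seeing the data, the margins were 14.6-fold for Gasz, 9.99-fold for zuc, 101-fold for del, 6.84-fold for fs(1)Yb, 13.7-fold for armi, 7.43-fold for w, 4.45-fold for aub and 7.03-fold for spn-E, since tj-armi held Gasz and fs(1)Yb reads of 23 nt and tj-w held zuc reads of 22 nt. The mRNA levels of the targets were not measured in these data.

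The nos-w and tj-w libraries were dominated by reads of 23 to 28 nt, the size of piRNAs, the germline and follicle cell small RNAs that silence transposons. These sizes made up 74.3% of reads (95% interval, exact Clopper-Pearson, 74.3 to 74.4%) in nos-w and 92.6% in tj-w, and transposon reads of every length made up 67.9% and 72.3%. Knockdown of armi, Gasz, spn-E or aub in germ cells was accompanied by a larger share of 21 nt reads, at 32.1%, 36.3%, 24.6% and 18.5% against 8.31% in nos-w. The nos-del share was 10.4%. Among the tj-GAL4 libraries, tj-armi stood apart with 25.9% of its reads at 23 nt, against 3.99 to 11.4% in the others. Fragments of structural RNAs took 2.49% of reads in nos-w, 6.26% in nos-spnE and 4.43% in nos-del, and 1.08% in tj-w against 3.32% in tj-armi. Of those of 23 to 28 nt, 71.7% in nos-spnE and 63.3% in nos-del started with U, against 52.1% in nos-w. Transposon reads of these sizes did so at 75.3% in nos-spnE and 73.4% in nos-del. The shares of structural RNA fragments may therefore not measure RNA quality alone.

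**Figure D1:**
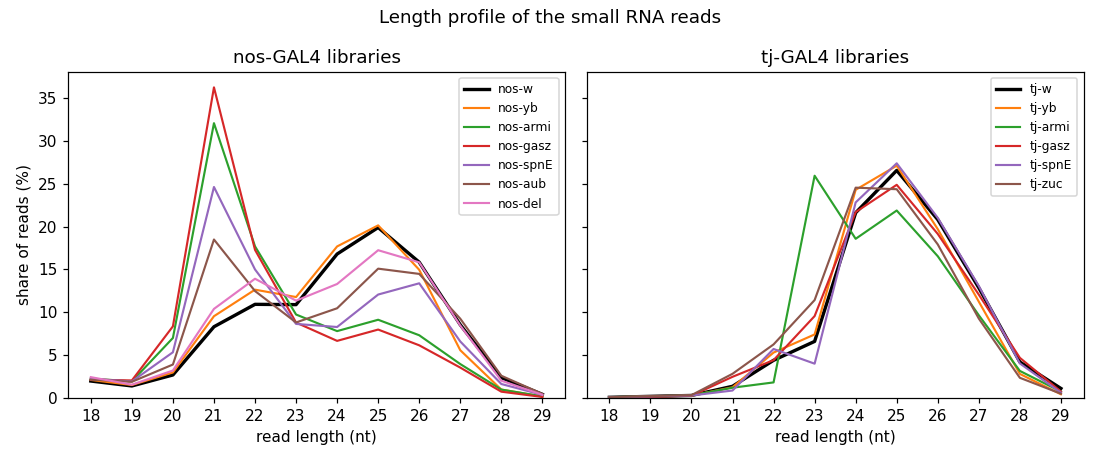
Share of reads (percent, y axis) at each length (nt, x axis) in the 13 libraries. The 21 nt share was 32.1% in nos-armi and 36.3% in nos-gasz against 8.31% in nos-w, and 25.9% of tj-armi reads were 23 nt long.

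Markers of other cells were followed in the miRNA reads. The muscle miRNA mir-1 made up 0.750% of miRNA reads in nos-w, 1.29% in nos-armi, 1.79% in nos-gasz and 1.46% in nos-del, while mir-133, also of muscle, stayed at or under 0.0038% in all 13 libraries. The neuronal mir-124 stayed at or under 0.0007%, and mir-7 lay between 0.142% and 0.533%. The tj-GAL4 libraries held 0.0078 to 0.0637% mir-1. Of the ovary miRNAs, mir-989 was the most abundant in nos-gasz at 13.9% and stood at 6.61% in nos-w, and mir-318 made up 20.6% in tj-w, 35.4% in tj-spnE and 4.51% in tj-armi. The miRNA composition of tj-armi differed from that of tj-w by 31.4% of reads, that of tj-spnE by 17.8%, and the composition of each other knockdown differed from its control by 5.91 to 15.2%.

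Levels of piRNAs are given relative to miRNA reads, as ratios to the w library of the same driver. A transposon family was called lower or higher when it differed at least 2-fold and its 95% interval excluded no change. Scaling to all reads instead would add 0.21 to the log2 ratios of nos-yb, 0.90 to those of nos-armi and nos-del, 0.82 for nos-gasz, 0.65 for nos-spnE and 0.45 for nos-aub. For tj-yb, tj-armi, tj-gasz, tj-spnE and tj-zuc it would add 0.45, 0.08, 0.10, 0.16 and 0.63. The deposited scaling would shift the 6 nos-GAL4 knockdowns, in the order above, by 0.37, -0.25, -0.47, -0.24, -0.52 and -0.92, and the 5 tj-GAL4 knockdowns by 0.43, 0.08, -0.14, 0.26 and 0.58. The difference between the germline and the soma list within a library does not depend on the scaling.

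Germline knockdown of fs(1)Yb, a Tudor domain gene of the follicle cells, left the transposon piRNAs close to the control. None of 123 families was called lower or higher. The median log2 ratio was -0.28 over all families, -0.30 over the 41 families of the germline list and -0.27 over the 8 families of the soma list, and under the deposited scaling the medians of both lists turned to 0.07 and 0.09. Total transposon piRNAs stood at 0.812 of nos-w (0.811 to 0.813), or 1.05 under the deposited scaling. The standard deviation of the log2 ratios across families was 0.19. It measures the scatter of families within this 1 pair of libraries, without their common shift, and not the spread between replicates.

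Germline knockdown of armi, an RNA helicase gene, or of Gasz, a gene of the outer mitochondrial membrane, removed most piRNAs of the germline transposons. Of 120 families, 108 fell in each knockdown and none rose. In nos-armi, 40 of the 41 germline list families fell, with a median log2 ratio of -4.93 (quartiles -6.27 and -2.75). The LTR retrotransposon invader6 fell 408-fold (347 to 482), the non-LTR elements Rt1a and Rt1b 234-fold and 211-fold, the DNA transposon pogo 206-fold and the telomeric HeT-A 197-fold. In nos-gasz the same number of germline list families fell (median -4.74, quartiles -6.47 and -3.14), among them Rt1b by 301-fold (284 to 320), invader6 by 237-fold and the I-element by 213-fold. Losses were smaller for roo, at 4.32-fold in nos-armi and 7.83-fold in nos-gasz, and for Burdock, at 6.34-fold and 8.82-fold. Total transposon piRNAs stood at 0.205 (0.205 to 0.205) and 0.182 (0.182 to 0.182) of nos-w.

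The soma list moved far less in nos-armi and nos-gasz. Of its 8 families, gypsy and Quasimodo fell, by 2.70-fold and 4.14-fold in nos-armi and by 2.66-fold and 2.02-fold in nos-gasz. Relative to all reads only Quasimodo in nos-armi was still called lower, and gypsy10 was called higher in both. The list's median log2 ratios were -0.31 and -0.29, and relative to all reads they turned to 0.59 and 0.53. The germline list median lay 24.6-fold below the soma list median in nos-armi and 21.8-fold below it in nos-gasz. The soma list made up 5.07% of transposon piRNAs in nos-w, 17.1% in nos-armi and 20.5% in nos-gasz. In the intermediate list, 8 of 11 families fell in each knockdown, such as blood by 3.92-fold and 3.94-fold. Against 10000 random lists of like abundance, the germline list median lay at percentiles 0.51 and 3.04. The soma list median lay at percentiles 100 and 99.99. An extreme percentile is no sign of a large change by itself. In nos-yb, where no family was called, the intermediate list median of -0.38 lay at percentile 0.

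Germline knockdown of spn-E, a Tudor domain helicase gene, lowered 100 of 122 families, and knockdown of aub, which encodes a Piwi family Argonaute protein, lowered 68 of 123, or 39 with each different sequence counted once. None rose in either. In nos-spnE, 37 of 41 germline list families fell with a median log2 ratio of -2.96 (quartiles -3.75 and -2.32), led by invader6 at 43.7-fold (40.7 to 47.0), pogo at 41.9-fold and the telomeric TAHRE at 39.4-fold. In nos-aub, 28 germline list families fell with a median of -1.41 (quartiles -1.89 and -0.87), led by pogo at 14.96-fold (13.6 to 16.5), invader6 at 9.71-fold and BS at 8.70-fold. HeT-A fell 28.6-fold in nos-spnE, while its ratio in nos-aub was 0.524 (0.518 to 0.529). Quasimodo was the only soma list family called in nos-spnE, 3.87-fold lower. In nos-aub no soma list family was called, but gypsy5 and Tabor were higher relative to all reads, and gypsy and Quasimodo lower under the deposited scaling. The soma list medians of -0.14 and 0.12 turned to 0.51 relative to all reads in nos-spnE and to -0.80 under the deposited scaling in nos-aub. The germline list median lay 7.04-fold below the soma list median in nos-spnE and 2.88-fold below it in nos-aub. Total transposon piRNAs stood at 0.275 (0.275 to 0.276) and 0.550 (0.549 to 0.551) of nos-w, and at 0.291 in nos-aub under the deposited scaling, where 110 families were lower.

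Germline knockdown of del, a gene needed for transcription of the dual-strand piRNA clusters, lowered 79 of 121 families and raised 5, and relative to all reads 61 fell and 14 rose. With each different sequence counted once 86 fell and none rose, and under the deposited scaling 87 fell and 2 rose. The first of these settings kept copies in the miRNA reads, 2106550 in nos-del against 949138 in nos-w. It can therefore lower the nos-del ratios by itself. No family rose in the other nos-GAL4 knockdowns, although relative to all reads 2 did in each of nos-armi, nos-gasz and nos-aub, and 1 in nos-spnE. The non-LTR element BS3 fell 59.9-fold (52.8 to 68.2), R2, which inserts into ribosomal DNA, 40.5-fold and invader6 29.4-fold. The families that rose were POGON1 at 6.24-fold (5.33 to 7.34), the LTR retrotransposons blood at 2.95-fold and TOM at 2.45-fold, Transpac at 2.12-fold, and S2 at 2.04-fold, the last chosen after its value was seen. Of the germline list, 31 families fell and Transpac rose (median log2 ratio -2.44, quartiles -3.41 and -1.17), while roo stood at 0.742 (0.738 to 0.747). Relative to all reads roo lay above nos-w. The intermediate list was mixed, with 4 of 11 families lower, blood higher and a median of -0.35 that turned to 0.54 relative to all reads. Quasimodo, 2.36-fold lower, was the only soma list family called, whereas gypsy10 and Tabor were called, as higher, relative to all reads. The germline list median lay 4.82-fold below that of the soma list, whose median of -0.18 turned to 0.72 relative to all reads. Total transposon piRNAs stood at 0.381 (0.380 to 0.381) of nos-w.

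**Figure D2:**
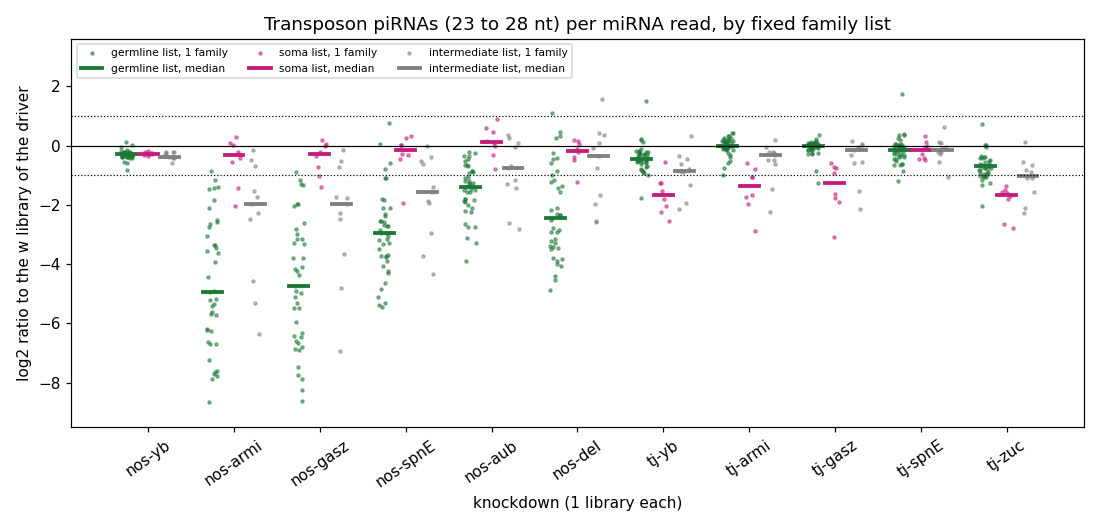
Log2 ratio of piRNA-sized reads per miRNA read to the w library of the same driver (y axis) for each family (points) and the median (bars) of the germline, soma and intermediate lists in the 11 knockdowns (x axis). The germline list stood at -4.93 in nos-armi and -4.74 in nos-gasz, and the soma list at -1.67 in tj-yb and -1.37 in tj-armi.

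Follicle cell knockdown of fs(1)Yb, armi, Gasz or zuc, which encodes a mitochondrial nuclease of the phospholipase D family, lowered the piRNAs of the soma list. In tj-yb, 7 of its 8 families fell (median log2 ratio -1.67, quartiles -2.10 and -1.26), in tj-armi 6 (median -1.37, quartiles -1.78 and -0.99), in tj-gasz 4 (median -1.27, quartiles -1.79 and -0.74) and in tj-zuc 8 (median -1.65, quartiles -2.01 and -1.54). The retrotransposon gtwin fell 5.88-fold (5.79 to 5.98) in tj-yb, 3.91-fold in tj-armi, 3.73-fold in tj-gasz and 6.82-fold in tj-zuc. For gypsy10 the falls were 4.78-fold, 7.45-fold, 8.53-fold and 6.30-fold. ZAM fell 2.91-fold in tj-yb, 2.09-fold in tj-armi and 3.27-fold in tj-zuc, and its ratio in tj-gasz was 0.604. Quasimodo fell 2.39-fold in tj-yb and 2.95-fold in tj-zuc, and gypsy fell 2.57-fold in tj-zuc. Relative to all reads, 5 soma list families were lower in tj-yb and 4 in each of tj-armi, tj-gasz and tj-zuc, gtwin, gypsy10 and gypsy5 in every case. Of the intermediate list, Stalker2 fell 4.42-fold, 4.71-fold, 4.43-fold and 4.86-fold, and DM412 fell 3.82-fold, 2.77-fold, 2.86-fold and 4.33-fold, in that order of libraries. TIRANT, which is in none of the lists, fell 3.55-fold, 3.31-fold, 3.27-fold and 4.40-fold.

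The germline list stayed near the control in these libraries or moved with the scaling. Its median log2 ratio was 0.00 in tj-armi and -0.01 in tj-gasz, with 1 of 41 families lower in each. These were rover, 2.00-fold lower in tj-armi, and the telomeric TART-B, 2.37-fold lower in tj-gasz. The rover call was lost relative to all reads and under the deposited scaling. Of the miRNA reads, 59.1% were 23 nt long in tj-armi against 28.4% in tj-w. For transposon reads these shares were 22.8% and 4.54%. The tj-armi list medians were not computed with 23 nt left out of both. In tj-yb the germline list median was -0.44 (0.01 relative to all reads), with pogo and invader1 lower and TART-B higher by 2.82-fold (2.79 to 2.85). The invader1 call was lost relative to all reads and under the deposited scaling. That of TART-B was lost with each different sequence counted once. In tj-zuc the germline list median was -0.70 (-0.07 relative to all reads) with 9 families lower, of which pogo was still lower relative to all reads. Total transposon piRNAs stood at 0.712 (0.711 to 0.713) of tj-w in tj-yb, 0.959 (0.958 to 0.960) in tj-armi, 0.923 (0.923 to 0.924) in tj-gasz and 0.602 (0.601 to 0.602) in tj-zuc. The tj-armi total had no stable direction, at 1.01 relative to all reads and under the deposited scaling, 0.775 at 24 to 27 nt and 1.32 at 24 to 28 nt relative to miRNA reads of 22 and 24 nt. Over all families, 21 of 127 fell and TART-B rose in tj-yb, 11 of 126 fell in tj-armi, 9 of 127 in tj-gasz and 38 of 127 in tj-zuc, and relative to all reads 12 families fell and 2 rose in tj-yb, 8 fell in tj-armi, and 11 fell and 2 rose in tj-zuc. In tj-armi 17 fell at 24 to 27 nt, and 8 fell and 5 rose at 24 to 28 nt relative to miRNA reads of 22 and 24 nt, an alternative chosen after seeing the data. The soma list median lay 2.35-fold below the germline list median in tj-yb, 2.59-fold in tj-armi, 2.41-fold in tj-gasz and 1.93-fold in tj-zuc.

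Follicle cell knockdown of spn-E left nearly all families within 2-fold of tj-w. Of 127 families, pogo fell 2.28-fold (2.18 to 2.39), DM176 2.06-fold and POGON1, chosen after its value was seen, 2.25-fold, and TART-B rose 3.34-fold (3.31 to 3.38). With each different sequence counted once, against miRNA reads with their copies, 1 family was lower and none higher, so the call of TART-B was lost. Under the deposited scaling none was called lower, and TART-B and G5, chosen after its value was seen, were higher. With other targets pogo also fell, 3.45-fold in tj-yb and 4.07-fold in tj-zuc. TART-B held 171677, 158828 and 106432 piRNA-sized reads in tj-yb, tj-spnE and tj-zuc, against 38272 in tj-w, 32365 in tj-armi and 22119 in tj-gasz. The shifts of pogo and TART-B were thus not particular to the spn-E knockdown, and their cause was not tested. The list medians were -0.14 for the germline, -0.16 for the soma and -0.14 for the intermediate list, and each turned to between 0.11 and 0.12 under the deposited scaling. Total transposon piRNAs stood at 0.911 (0.911 to 0.912), or 1.02 relative to all reads and 1.09 under the deposited scaling. The standard deviation of the log2 ratios across families was 0.38, wider than the 0.19 between nos-yb and nos-w, and 123 families lay within 2-fold.

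The 3' UTR of tj, the transcription factor gene traffic jam, is a source of piRNAs in follicle cells. Its piRNA-sized reads fell 46.3-fold (28.4 to 81.4) in tj-armi, 18.8-fold in tj-zuc, 11.5-fold in tj-gasz and 6.23-fold in tj-yb, from 972 reads in tj-w. In tj-spnE the ratio was 0.798 (0.730 to 0.874). In the nos-GAL4 knockdowns it lay between 0.830 and 1.64, and scaling turned its direction in 5 of the 6. It was 1.78 relative to all reads in nos-armi, and under the deposited scaling it was 1.07 in nos-yb and 0.866 to 0.979 in nos-spnE, nos-aub and nos-del. In nos-gasz it was 2.12 relative to all reads and 1.02 under the deposited scaling. Over all gene 3' UTRs with enough reads, 74 of 217 fell in tj-yb, 67 of 113 in tj-armi and 77 of 161 in tj-gasz. In tj-zuc 92 of 152 fell and in tj-spnE 3 of 211. In that order of libraries, 10, 4, 2, 3 and 1 rose. The summed reads of 3' UTRs other than tj stood at 0.632, 1.07, 0.618, 0.495 and 0.876 of tj-w, in the same order. Relative to all reads these ratios were 0.862, 1.12, 0.660, 0.768 and 0.978. The sum thus did not fall in tj-armi.

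**Figure D3:**
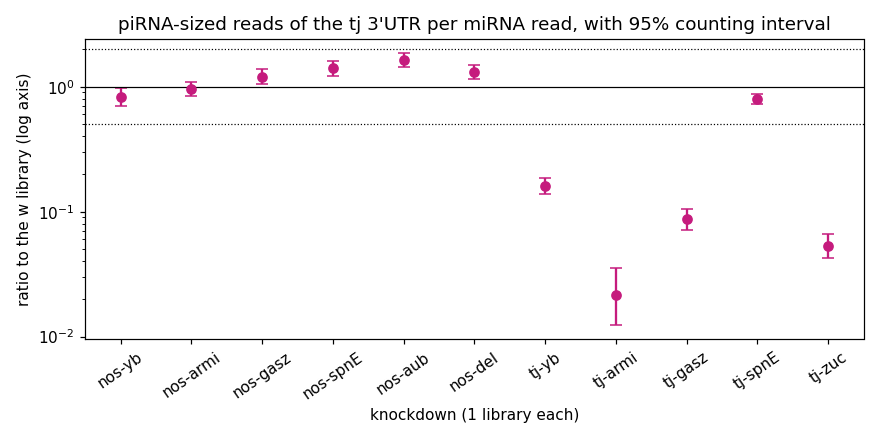
Reads of 23 to 28 nt on the tj 3' UTR as a ratio to the w library of the same driver (y axis, log scale) in the 11 knockdowns (x axis), with exact 95% intervals for counting error. The ratio was 0.0216 in tj-armi and 0.0533 in tj-zuc, and lay between 0.830 and 1.64 in the nos-GAL4 knockdowns.

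Gene exon reads went different ways in the nos-GAL4 knockdowns. In nos-armi, 152 of 278 gene parts fell and 1 rose, and in nos-gasz 132 of 224 fell and none rose. In nos-spnE, 438 of 692 gene parts rose and 43 fell. In nos-del, 725 of 1156 rose and 42 fell. In nos-aub, 61 of 411 rose and 52 fell, and in nos-yb 3 of 290 fell and none rose. Such counts favour rises under either driver, since a part with few reads in the control is counted only if it rises. Of the 127 parts with at least 100 reads in nos-w, a choice made after seeing the data that favours falls, 30 rose and 36 fell in nos-spnE, 18 rose and 33 fell in nos-del, and 3 rose and 40 fell in nos-aub, while 96 fell in nos-armi and 100 in nos-gasz. The summed reads of 3' UTRs other than tj stood at 2.10 (2.08 to 2.12) in nos-spnE and 1.53 (1.52 to 1.55) in nos-del, against 0.515 in nos-armi and 0.400 in nos-gasz. Relative to all reads these ratios were 3.30, 2.86, 0.958 and 0.707. Structural RNA fragments were also more frequent in nos-spnE and nos-del, at 6.26% and 4.43% of reads. In the tj-GAL4 knockdowns 168 gene parts of 944 fell and 64 rose in tj-yb, 140 of 624 fell and 41 rose in tj-armi, 149 of 831 fell and 26 rose in tj-gasz, 231 of 806 fell and 19 rose in tj-zuc, and 31 of 852 fell and 12 rose in tj-spnE.

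The same 4 targets were compared between drivers. For armi the germline list median was -4.93 under nos-GAL4 and 0.00 under tj-GAL4, while the soma list median was -0.31 and -1.37. For Gasz the germline list stood at -4.74 and -0.01 and the soma list at -0.29 and -1.27. For spn-E the germline list stood at -2.96 and -0.14, and both soma list medians lay near -0.15, at -0.14 and -0.16. For fs(1)Yb the germline list stood at -0.30 and -0.44 and the soma list at -0.27 and -1.67. These differences between drivers were not tested, and the controls themselves differed, with 64 of 125 families higher in tj-w than in nos-w and a median log2 ratio of 1.05.

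The ping-pong signature, a 10 nt overlap between the 5' ends of complementary piRNAs that arises when they are made from each other's cleavage products, depended on the germline target. Of transposon read pairs with overlaps of 10 to 20 nt, 64.8% overlapped by 10 nt in nos-w, against 9.09% if all overlaps were equally frequent. The share was 64.4% in nos-yb, 80.1% in nos-armi and 80.4% in nos-gasz, and it was lower at 31.3% in nos-spnE, 38.04% in nos-aub and 50.9% in nos-del. These shares pool the pairs of all families. Of 39 germline list families with pairs in every library, the share was above that of nos-w for 20 in nos-armi and 24 in nos-gasz. It was below that of nos-w for 19 and 15, such as the I-element at 63.3% in nos-w and 9.76% in nos-armi. The I-element held only 258 piRNA-sized reads in nos-armi, against 17500 in nos-w. Invader6 and pogo, at a share of 0% in nos-armi, held 148 and 51 reads there. Shares below nos-w can thus rest on few reads. In nos-spnE and nos-aub the share was below that of nos-w for all 39. Pooled over the soma list it was 62.5% in nos-w, 14.7% in nos-armi, 21.4% in nos-gasz, 9.46% in nos-spnE, 33.5% in nos-aub, 50.3% in nos-del and 61.4% in nos-yb. The value in nos-w reflects Idefix, gypsy and Quasimodo, at 61.8% to 72.3%, while the other 5 families lay between 6.37% and 24.9%, and ZAM was at 34.3% in nos-armi. Among germline list reads that did not start with U, 43.7% had A at position 10, counted from the 5' end, in nos-w, 63.4% in nos-armi, 67.8% in nos-gasz, 29.4% in nos-spnE and 37.1% in nos-aub. In the tj-GAL4 libraries the share of 10 nt overlaps lay between 57.6% and 65.3%. With each different sequence counted once, the shares were lower, at 17.8% in nos-w, 26.5% in nos-armi, 31.3% in nos-gasz, 10.8% in nos-spnE and 12.1% in nos-aub.

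**Figure D4:**
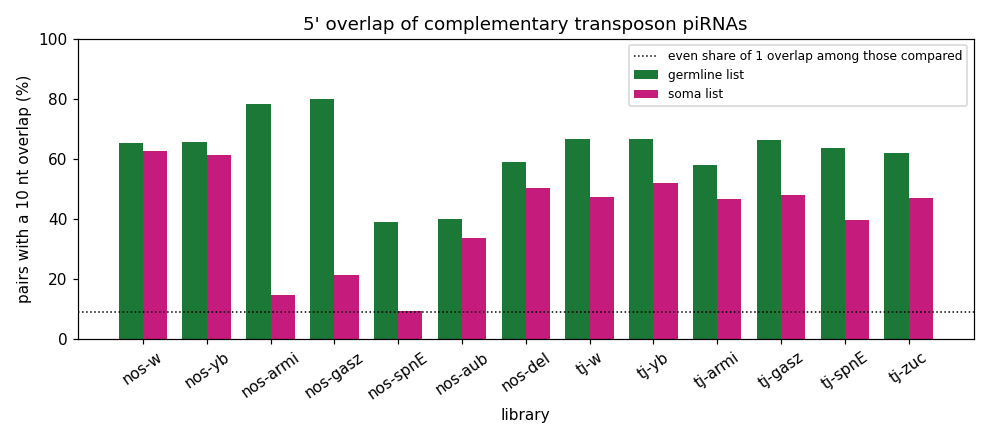
Share of transposon read pairs with a 10 nt overlap among overlaps of 10 to 20 nt (percent, y axis) in the 13 libraries (x axis), as bars for the germline and soma lists, with a dotted line at 9.09%. The share pooled over the soma list was 62.5% in nos-w, where the median of its 8 families was 20.5%, and 14.7% in nos-armi and 9.46% in nos-spnE.

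Transposon reads of 21 nt, the size of siRNAs made by Dicer-2, were more abundant in the germline knockdowns of armi, Gasz, spn-E and aub. Their level was 2.78 times that of nos-w (2.77 to 2.79) in nos-armi, 3.17 times in nos-gasz, 2.30 times in nos-spnE and 2.04 times in nos-aub, the last falling to 1.08 under the deposited scaling. In nos-del the ratio was 0.571 (0.568 to 0.574), or 1.06 relative to all reads, and in nos-yb 1.02. The rise was not confined to families that lost piRNAs. In nos-armi, nos-gasz, nos-spnE and nos-aub, 21 nt reads of the soma list stood at 2.61, 3.56, 1.94 and 1.97 times nos-w. Those of the germline list stood at 2.60, 2.88, 2.26 and 2.19 times, in that order. Across families, 98 of 120 rose in nos-armi, 112 of 123 in nos-gasz, 68 of 117 in nos-spnE and 75 of 118 in nos-aub, while 86 of 110 fell and 6 rose in nos-del. Burdock 21 nt reads rose 4.15-fold to 7.22-fold in these 5 knockdowns and diver 4.53-fold to 8.21-fold. HeT-A 21 nt reads fell to 0.498 in nos-gasz and 0.317 in nos-spnE and rose 2.204-fold in nos-aub. The nos-gasz fall was under 2-fold relative to all reads, and the nos-aub rise was under 2-fold with the deposited scaling. The hairpin siRNA loci esi-1 and esi-2 stayed between 0.810 and 1.23 times nos-w in the nos-GAL4 knockdowns, while esi-4 rose 2.97-fold to 9.38-fold in 5 of the 6. In the tj-GAL4 libraries the 21 nt transposon ratio lay between 0.656 in tj-spnE and 1.83 in tj-gasz, where reads of other libraries' targets were also present at 21 nt.

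**Figure D5:**
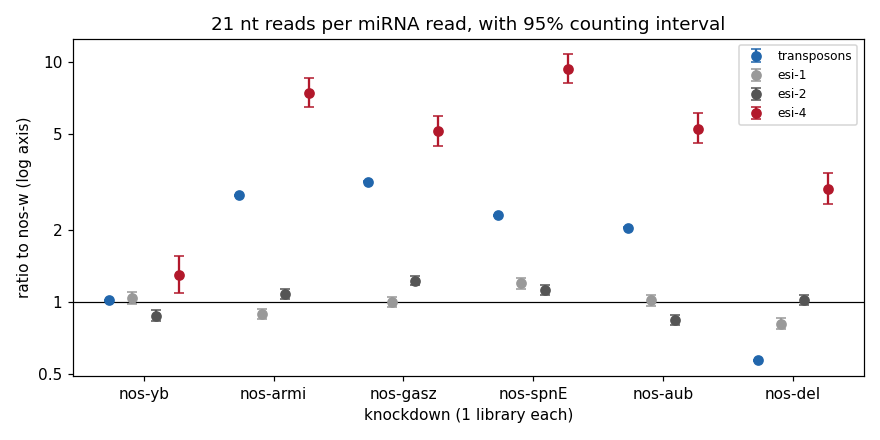
Reads of 21 nt on transposons, esi-1, esi-2 and esi-4 per miRNA read, as a ratio to nos-w (y axis, log scale), in the 6 nos-GAL4 knockdowns (x axis), with exact 95% intervals for counting error. The transposon ratio was 3.17 in nos-gasz, 2.78 in nos-armi and 0.571 in nos-del, the last turning to 1.06 relative to all reads.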

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

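All tests of an explanation in this part were chosen after the result was seen, except the comparison of gene reads with structural RNA fragments, which was set beforehand.

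Several results were flagged because their log2 ratios had opposite signs under the 2 drivers, some of them near 0 under 1 driver. None of these differences was tested, since each rests on 1 library per driver and target. The germline list median of the armi knockdown differed by -4.93 on the log2 scale, from -4.93 under nos-GAL4 to 0.00 under tj-GAL4. This was a fall against no change. Gasz, at -4.74 and -0.01, was alike but was not flagged, since both values were below 0. For spn-E, TART-B piRNAs differed by -4.92, at -3.17 under nos-GAL4 and 1.74 under tj-GAL4. TART-B piRNAs also rose in tj-yb, so their rise under tj-GAL4 was not particular to spn-E. The 21 nt transposon reads differed by 1.81 for spn-E (1.202 and -0.61) and by 0.50 for fs(1)Yb (0.02 and -0.47). Reads of 23 to 28 nt of the tj 3' UTR differed by 3.79 for Gasz (0.27 and -3.52) and by 0.81 for spn-E (0.49 and -0.32). The nos-GAL4 value for spn-E turned below 0 under the deposited scaling.

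Reads of 21 to 23 nt from genes that a library did not target appeared in 5 tj-GAL4 libraries, above the median of the other tj-GAL4 libraries that did not target the gene. In tj-armi there were 2630 such reads of Gasz, 790 of aub and 677 of fs(1)Yb, and in tj-gasz 1018 of armi, 1432 of aub and 218 of fs(1)Yb. In tj-w there were 1266 of zuc, in tj-yb 659 of Gasz and 341 of armi, and in tj-zuc 1585 of spn-E. Of the 11 sets, which include w reads in tj-zuc, 9 had at least 90% of their reads at 1 length, such as 98.0% of the Gasz reads in tj-armi at 23 nt. The aub sets were compared with nos-aub, a library of the other driver that holds only 99 such reads at 23 nt against 780 in tj-armi.

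For the sets in tj-armi, tj-gasz and tj-zuc, reads of finished libraries given to the wrong library would keep the length profile of their source, but their share at the commonest length exceeded that of the source by a median of 62.7 points (lowest 15.2, or 36.5 with sources of the same driver). A second hairpin transgene would give the profile of the library's own hairpin siRNAs, but that was exceeded by a median of 25.3 points (lowest 22.01). RNA of 1 size carried in from another sample before sequencing could not be told apart from other sources. Transposon reads at that length were in excess by a median of 2.26 times the other tj-GAL4 libraries, but at 4.60, 1.94 and 2.26 against an expected 2.00, 3.74 and 1.21. The expected values took only the largest foreign set of each library, Gasz in tj-armi, aub in tj-gasz and w in tj-zuc. The source for aub was nos-aub, of the other driver, and the other sets were left out. The mismatch can come from that choice, so it does not count against carried RNA. In tj-w the excesses of 81.9 points over the source and 55.8 over the own hairpin argue against both of the first accounts, and carried RNA stays open, since transposon reads at 0.903 of the others were set against an expected 1.44, short of the 1.5 the test needs. In tj-yb none of the accounts could be told apart, with median excesses of 17.2 points (4.58 and 29.9) and 16.1 points (13.3 and 19.0). Transposon reads there stood at 0.811, where carried RNA of the largest set, that of Gasz, would give only 1.02.

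The rise of 21 nt transposon reads in nos-armi, nos-gasz, nos-spnE and nos-aub was weighed next. Better recovery of 21 nt RNA in the size selection would raise all siRNA loci alike, but the median ratio of esi-1 and esi-2 was 1.05 (0.840 to 1.23), while esi-4 rose 5.17-fold to 9.38-fold. Degraded RNA would raise transposon reads of 18 and 19 nt as much, but the 21 nt ratio exceeded theirs by a median of 3.95 times (2.14 to 4.76). Cleavage of double-stranded transposon RNA by Dicer-2 could not be told apart from other sources. Pooled over all families, the share of pairs with a 19 nt overlap exceeded nos-w by as little as 0.881 points and by at most 2.96. For the germline list it was 5.60% in nos-w, 11.3% in nos-armi, 13.4% in nos-gasz, 10.3% in nos-spnE and 8.64% in nos-aub. With each sequence counted once these shares were 8.71%, 9.45%, 9.59%, 9.06% and 9.04%. Over all families 19 nt was the commonest overlap in nos-armi and nos-gasz, but not in nos-spnE or nos-aub. The libraries' own hairpin siRNAs, a known Dicer-2 product, reached only 8.57 to 13.3% themselves.

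The rise of summed gene exon reads in nos-spnE and nos-del, where most gene parts with at least 100 reads in nos-w were not called higher, was weighed last. A larger share of follicle cell RNA would raise the soma list, but its median log2 ratio was -0.14 in nos-spnE and -0.18 in nos-del, although it is 0.51 and 0.72 relative to all reads, where the gene parts rise by as much again. Fragments of degraded mRNA were not settled by the planned comparison. The gene parts start with U about as often as structural RNA fragments do, with an excess of -1.54 points in nos-del and 4.51 in nos-spnE. That reference is itself rich in U in these libraries, at 63.3% and 71.7% against 52.1% in nos-w and 19.8% in nos-gasz. The comparison therefore separates the accounts poorly. The parts raised in nos-spnE started with U in 76.6% of reads in nos-w and 76.2% in nos-spnE. For those raised in nos-del the shares were 65.9% in nos-w and 61.7% in nos-del. The added reads kept most of this U share, which argues against breakage without a preference for U as their main source. Breakage that favours U stays open. Production of piRNAs from gene transcripts stays open as a hypothesis too, since the U share lay at most 11.7 points under that of transposon reads, at 61.7% in nos-del and 76.2% in nos-spnE.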

How the results depend on the processing

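The authors' deposited scaling, the centring on a list, and the range of 24 to 28 nt with miRNA reads of 22 and 24 nt were tests chosen after seeing the data. So were the scaling to all reads for list medians and 21 nt ratios, and 24 to 27 nt for list medians. The others were planned. More families were lower than higher in the main result of every knockdown but nos-yb. This turned to the opposite only in tj-spnE with the deposited scaling and in the 5 tj-GAL4 knockdowns against the control of the other driver, while ratios near 1 crossed it more often. Where values moved, the cause was not tested. Requiring no minimum or at least 1000 reads left all 11 counts within 1.5 times. Uniquely placed reads only, antisense reads only and both alternatives for piRNA clusters were not run, since the files hold no positions or strands. No paired analysis was possible because the result comes from no test, with 1 library per group. Depth limited the tj 3' UTR in tj-armi, which rests on 16 reads.

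Relative to all reads, the families lower were 12 in tj-yb (21 relative to miRNA reads) and 11 in tj-zuc (38), and families lower and higher were 61 and 14 in nos-del (79 and 5), 11 and 2 in tj-zuc (38 and 0) and 2 and 2 in tj-spnE (3 and 1). The transposon piRNA ratios were 0.942 in nos-yb, 0.382 in nos-armi, 0.321 in nos-gasz, 0.433 in nos-spnE, 0.749 in nos-aub, 0.709 in nos-del, 0.971 in tj-yb, 1.01 in tj-armi, 0.986 in tj-gasz, 1.02 in tj-spnE and 0.933 in tj-zuc. With the deposited scaling, the families lower were 110 in nos-aub (68), 87 in nos-del with 2 higher, 12 in tj-yb with 2 higher, 0 in tj-spnE with 2 higher, and 12 in tj-zuc with 2 higher. The ratios were 1.05 in nos-yb, 0.172 in nos-armi, 0.154 in nos-gasz, 0.192 in nos-spnE, 0.291 in nos-aub, 0.275 in nos-del, 0.959 in tj-yb, 1.01 in tj-armi, 0.840 in tj-gasz, 1.09 in tj-spnE and 0.896 in tj-zuc. Centred on the list of the untargeted cell type, the families lower were 12 in tj-yb and 10 in tj-zuc with 2 higher. The ratios were 0.981 in nos-yb, 0.254 in nos-armi, 0.223 in nos-gasz, 0.304 in nos-spnE, 0.508 in nos-aub, 0.430 in nos-del, 0.964 in tj-yb, 0.927 in tj-gasz, 1.005 in tj-spnE and 0.980 in tj-zuc.

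At 24 to 27 nt, 17 families were lower in tj-armi (11), and the ratios were 0.816 in nos-yb, 0.206 in nos-armi, 0.184 in nos-gasz, 0.288 in nos-spnE, 0.568 in nos-aub, 0.394 in nos-del, 0.719 in tj-yb, 0.775 in tj-armi, 0.884 in tj-gasz, 0.930 in tj-spnE and 0.578 in tj-zuc. At 24 to 28 nt relative to miRNA reads of 22 and 24 nt, the families lower and higher were 6 and 1 in tj-spnE (3 and 1) and 8 and 5 in tj-armi (11 and 0), and the ratios were 0.677 in tj-yb, 1.32 in tj-armi, 0.951 in tj-gasz, 0.760 in tj-spnE and 0.547 in tj-zuc. With each different sequence counted once, 39 families were lower in nos-aub and 1 in tj-spnE, and the families higher fell from 5 to 0 in nos-del and from 1 to 0 in tj-yb and tj-spnE, and the ratios were 0.865 in nos-yb, 0.159 in nos-armi, 0.162 in nos-gasz, 0.397 in nos-spnE, 0.699 in nos-aub, 0.330 in nos-del, 0.647 in tj-yb, 0.703 in tj-armi, 0.870 in tj-gasz, 0.839 in tj-spnE and 0.604 in tj-zuc.

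Against the control of the other driver, whose libraries differ in depth and size profile, 84 families were lower in nos-yb (0) and 114 in nos-aub (68). The families lower and higher were 5 and 23 in tj-yb, 4 and 48 in tj-armi, 3 and 49 in tj-gasz, 1 and 50 in tj-spnE, and 9 and 13 in tj-zuc. The ratios were 0.399 in nos-yb, 0.101 in nos-armi, 0.0895 in nos-gasz, 0.135 in nos-spnE, 0.271 in nos-aub, 0.187 in nos-del, 1.45 in tj-yb, 1.95 in tj-armi, 1.88 in tj-gasz, 1.85 in tj-spnE and 1.22 in tj-zuc.

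Of the other values, 33 of 33 list medians stayed within a fixed margin on the log2 scale with a pseudocount of 10 reads. At 24 to 27 nt 28 did and 5 moved. Relative to all reads 46 of 55 list medians, 21 nt ratios and tj 3' UTR ratios moved, and 50 did with the deposited scaling. Ping-pong shares stayed in 34 of 39 cases when thinned to the shallowest library, and moved in 38 with each sequence counted once.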

Other observations

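The features named in this part were chosen after their values were seen, and no explanation of them was tested. Satellite repeats differed between the germline knockdowns. piRNA-sized reads of HETRP stood at 0.103 of nos-w in nos-armi, 0.0575 in nos-gasz, 0.0424 in nos-spnE and 0.0427 in nos-del, at 0.462 in nos-aub and at 0.764 in nos-yb. Those of the Responder satellite RSP stood at 0.0929 in nos-gasz (0.0810 to 0.106), 0.0420 in nos-del, 0.421 in nos-spnE, 0.407 in nos-aub, 0.610 in nos-armi and 0.879 in nos-yb. The SAR_DM satellite stood at 0.264 in nos-gasz, 0.266 in nos-spnE, 0.274 in nos-del, 0.587 in nos-armi, 0.675 in nos-aub and 0.756 in nos-yb. Relative to all reads, RSP and SAR_DM in nos-armi turned to 1.14 and 1.09, and RSP in nos-yb to 1.02. In the tj-GAL4 knockdowns HETRP lay between 0.718 and 1.05 and RSP between 0.982 and 1.33, but relative to all reads HETRP turned to 1.26 in tj-yb and 1.42 in tj-zuc, RSP turned to 1.04 in tj-armi, and RSP reached 1.82 in tj-yb. Reads of the unnamed genes CG41562 and CG40813 fell in 5 of the 6 nos-GAL4 knockdowns, as CG40813 did by 137-fold in nos-armi, 72.5-fold in nos-gasz, 13.8-fold in nos-spnE, 6.68-fold in nos-aub and 135-fold in nos-del.

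Individual genes stood out among the gene exon reads. In nos-spnE, piRNA-sized reads of Dcr-2, the Dicer of the siRNA pathway, were 14.9 times nos-w (13.2 to 16.7), and those of spi, an EGF receptor ligand gene, 17.8 times (14.4 to 22.3). In nos-del, the 3' UTR of r2d2, whose protein is the partner of Dicer-2, went from 2 to 1612 reads, a ratio of 363 with a counting interval of 100.4 to 3001, and that of Ada2b from 9 to 2431 reads, a ratio of 122 (64.0 to 266). In the follicle cell knockdowns, reads of CG32000 fell 15.8-fold in tj-yb, 28.9-fold in tj-armi, 16.3-fold in tj-gasz and 12.7-fold in tj-zuc. The 3' UTR of Sug fell 6.98-fold, 89.1-fold, 12.7-fold and 10.3-fold in the same order. The hairpin locus esi-4 gave more 21 nt reads in 5 of the 6 nos-GAL4 knockdowns, from 2.97 times nos-w in nos-del to 9.38 times in nos-spnE, and 1.299 times in nos-yb. Transpac had the largest 21 nt ratio of all families in 5 of the 6, at 46.7 in nos-armi, 28.1 in nos-gasz, 39.9 in nos-spnE, 9.34 in nos-aub and 64.9 in nos-del.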
